A study of Mus musculus with 12 samples.

How the data were processed

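Messenger RNA was measured by RNA sequencing in 12 libraries from bone marrow monocytes of wild-type C57Bl6J mice. The libraries fall in 4 groups of 3: untreated cells, cells kept overnight with platelets and washed, cells given lipopolysaccharide (LPS), and cells kept overnight with platelets, washed and then given LPS. Group and replicate number were taken from the titles and treatment labels. Platelet replicate 1 is described as "Control" in its description field, while its title and treatment label name platelets. It was kept in the platelet group, and results without it are given. The doses of platelets and LPS and the time with LPS are not given in the sources used here.

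Per the labels, RNA was isolated with the RNeasy Plus Micro kit, amplified with the SMARTer Ultra Low Input v4 kit and made into Nextera XT libraries. The submitters' processing notes name fastp 0.23.1, STAR 2.7.9a, Subread 2.0.1 with featureCounts, and Salmon 1.5.2, without saying which made the deposited files. The deposited files hold whole-number read counts per gene, not normalized, for 53819 genes in each library. The genome build, annotation release and strand setting are not given in the sources used here, so no positions are printed. Of the gene names, 49948 were found among the gene symbols of GENCODE M21, 1442 were Ensembl IDs and 2429 were neither. M21 served only to look up names and gene types. Reads shared between near-identical genes, such as the alpha globin genes Hba-a1 and Hba-a2, cannot be assigned from these counts.

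Of 26048 genes with a count in any library, 13151 passed the filterByExpr function of edgeR 4.0.16 and were tested. Counts were scaled by the trimmed mean of M-values (TMM) and fitted in R 4.3.3 with edgeR's quasi-likelihood model, with all 12 libraries in a single fit of 4 group means that left 8 residual degrees of freedom. Tests were two-sided, and p-values were adjusted by the Benjamini-Hochberg method over the genes tested, with a threshold of 0.05. The common dispersion was 0.0171. The 7 contrasts were platelet against untreated, LPS against untreated, platelet plus LPS against LPS, platelet plus LPS against platelet, their interaction (the platelet effect with LPS minus that without), and the average platelet and LPS effects. Levels are in CPM, with the TMM-scaled library size as the total, given as mean ± SD with n = 3 per group. Fold changes and log2 values come from the fit, with a standard error (SE) from its F statistic.

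Before the data were examined, 31 gene lists (23 of cell state or RNA quality and 8 of cell type markers), the contrasts, most alternatives and a rule for the genes to name were fixed. The lists hold 813 members, of which 811 were found in the files and 708 were tested. Rigi was looked up under its older name Ddx58. Each list was tested against the other genes with camera of limma 3.58.1 on log2 CPM with a prior count of 2 and a preset correlation of 0.01, adjusted over the 30 lists with enough tested members, and again with an estimated correlation. The rotation test fry was run as well. Counts of list members called are given by the p-value adjusted over all genes tested and, separately, adjusted over the list alone. Genes that rose or fell in the average LPS effect were also tested as sets in the platelet contrasts. These sets were chosen on the same libraries.

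The genes named are the 6 largest rises and 6 largest falls of each contrast and 20 genes fixed in advance. Up to 4 members of each described list, by smallest p, are named as well. The largest rises and falls had an adjusted p under 0.05 and a mean of at least 10 CPM in the higher group, without predicted genes and pseudogenes. No overlap between replicates was also required for comparisons of 2 groups, but not for the interaction or the average effects. Some genes that the rule takes are withheld for evaluation and left out of the text and figures. Any other gene is said to have been chosen after its values were seen. A fold against a group with no counts is a lower bound, computed with 3 counts in each of its libraries, and a fold against a group with 1 to 3 counts is given with its 95% counting interval. These floors and intervals cover counting error only, since reads amplified by PCR without molecular identifiers are not independent molecules.

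Alternatives were DESeq2 size factors, upper-quartile factors or library size alone in edgeR, no filter or a stricter filter (at least 1 CPM in 3 libraries and at least 10 counts in 3), a replicate block, the Wald test of DESeq2 1.42.0, limma-voom, an absolute log2 fold change of at least 1, only the 2 groups compared, and leaving out each library in turn. Scaling and filter alternatives for the lists and sets, and list counts without platelet replicate 1, were added after the data were seen. The method was tested on simulated counts with the fitted dispersions. The changed genes, 66 or 67 per fold and of random direction, were drawn from those with a mean of at least 1 CPM. At a 2-fold change edgeR recovered 85.1% of changed genes for platelet against untreated, 79.1% for LPS against untreated, 82.1% for platelet plus LPS against either single treatment, and 56.7% for the interaction. At 1.5-fold it recovered 59.7%, 55.2%, 50.7% (against LPS), 49.3% (against platelet) and 10.4% in that order, and 3.16 to 6.19% of its calls over all 7 contrasts were false. The recovered shares do not cover genes below 1 CPM. Counts were drawn independently for each gene, so no simulated library departed as a whole from its replicates as platelet replicate 1 did. Neither recovery nor false calls were tested with as many changes as LPS gave in the real data, 6661 genes against untreated. The other tests are described where they are reported, and no library or column was left out.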

Results

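RNA was sequenced from mouse bone marrow monocytes that had or had not been kept overnight with platelets, and then had or had not been given lipopolysaccharide (LPS), the bacterial product sensed by Toll-like receptor 4. Each of the 4 groups has 3 libraries, with total counts of 20060867 to 32155727 per library, so that 3 counts correspond to 0.0854 to 0.1635 CPM. The labels do not say whether the libraries of a group came from separate mice or cultures, so the p-values measure only the spread between these libraries, which may be technical. LPS separated the libraries on the first principal component, which held 77.9% of the variance. Platelet exposure separated them on the second, which held 6.82%: the 6 exposed libraries scored 15.3 to 35.6 and the 6 unexposed libraries −30.4 to −17.4. Platelet replicate 1 stood apart from the other 2 platelet libraries, with 35.6 on the second component, 0.886% mitochondrial counts against 0.431 to 0.600% in the other libraries, and a chi-square per degree of freedom of 76.2 and 83.5 against its replicates, where other pairs within groups gave 6.75 to 21.6.

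**Figure D1:**
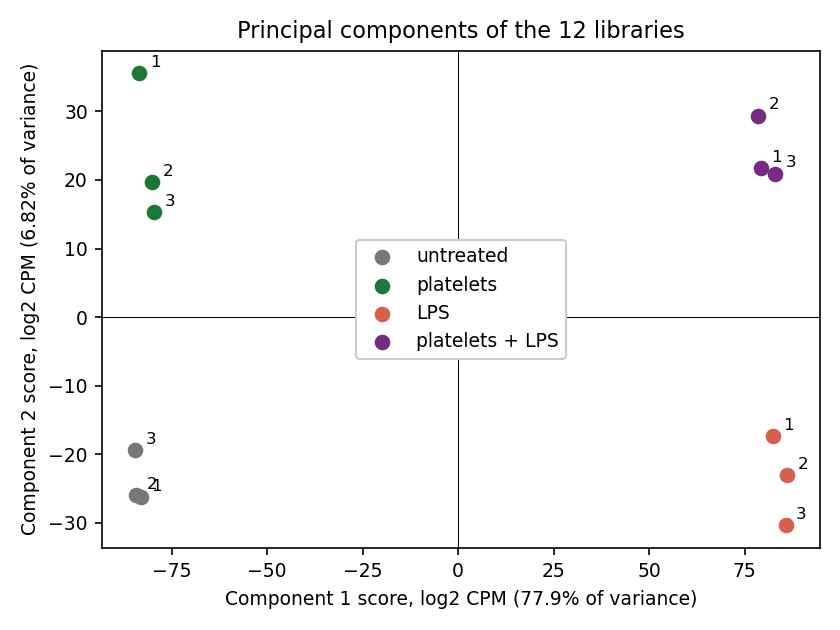
Scores of the 12 libraries on the first and second principal components of log2 CPM, with the replicate number beside each point and colour for the group. The second component runs from 15.3 to 35.6 in the 6 platelet-exposed libraries, with platelet replicate 1 at the upper end, and from −30.4 to −17.4 in the 6 others.

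The first question is which genes overnight contact with platelets changed in monocytes not given LPS. Genes of cholesterol synthesis and uptake fell together. Sqle, an enzyme of cholesterol synthesis, was 3.54-fold lower with platelets, at 42.6 ± 9.44 CPM against 151 ± 3.24 CPM in untreated cells (log2 −1.82, SE 0.14, adjusted p = 5.61e-07). The synthesis enzymes Cyp51 and Msmo1 had log2 fold changes of −1.83 and −1.38. Of 24 tested members of the cholesterol biosynthesis and uptake list, 19 were lower and 0 higher over all genes tested, and 22 were lower and 0 higher adjusted over the list alone. EdgeR at an unadjusted p under 0.05, DESeq2 and limma-voom also called 0 higher. The median log2 fold change was −1.28 (camera adjusted p = 1.67e-28, adjusted p = 0.00354 with an estimated correlation).

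Targets of the liver X receptor (LXR), which is activated by oxidised cholesterol, rose in the same libraries. Abca1 and Abcg1, which export cholesterol, were 15.7-fold (SE 0.20 on the log2 scale, adjusted p = 9.26e-09) and 25.8-fold (SE 0.28, adjusted p = 5.42e-08) higher, Abca1 going from 6.48 ± 1.85 to 102 ± 4.92 CPM. Pltp and Apoe, which carry lipids in lipoproteins, were 4.12-fold and 2.48-fold higher. Of 17 tested members of the list of LXR targets and lipid efflux or storage, 8 were higher and 1 lower, and 9 and 1 adjusted over the list alone, with a median of 0.37 (camera adjusted p = 1.56e-06, adjusted p = 0.00606 with an estimated correlation). The lower member was Fasn, which makes fatty acids, at log2 −1.02 (adjusted p = 0.00229), and it is named after its values were seen. Platelet replicate 1, with the highest platelet marker levels, had 96.2 CPM of Abca1 against 102 and 106 CPM in its replicates. Without it 21 cholesterol genes were lower, with 8 members of the LXR list higher and 1 lower.

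Antigen presentation and low-oxygen genes were also higher with platelets. H2-Ab1, a chain of the MHC class II molecule that presents peptides to helper T cells, rose 2.23-fold, from 54.0 ± 5.68 to 121 ± 20.9 CPM (SE 0.12, adjusted p = 1.44e-05), with H2-Aa at 2.08-fold. Of 17 MHC class II genes, 7 were higher and 0 lower (12 and 0 adjusted over the list alone, 12 and 0 at an unadjusted p under 0.05, 10 and 0 by DESeq2, 7 and 0 by limma-voom), with a median of 0.62 (camera adjusted p = 2.25e-10, adjusted p = 0.0245 with an estimated correlation). Markers of dendritic cells, which carry MHC class II, were higher in the same comparison, 3 of 15 with a median of 1.13 (camera adjusted p = 2.84e-05, adjusted p = 0.0108 with an estimated correlation). B2m, the shared chain of MHC class I, rose 1.56-fold, and 7 of 20 MHC class I genes were higher and 0 lower (11 and 0 adjusted over the list alone, median 0.25, camera adjusted p = 6.74e-07, adjusted p = 0.0245 with an estimated correlation). Egln3, an oxygen-sensing hydroxylase, and Vegfa, a growth factor for blood vessels, rose 6.03-fold and 2.58-fold. Of 30 glycolysis and hypoxia genes, 16 were higher and 0 lower (19 and 0 adjusted over the list alone, median 0.29, camera adjusted p = 1.65e-12, adjusted p = 0.0245 with an estimated correlation). The cell cycle list had 8 of 39 members higher and 0 lower, among them Ube2c and Ccnb1 at 1.35-fold and 1.32-fold (15 and 0 adjusted over the list alone, median 0.23, camera adjusted p = 2.2e-07, adjusted p = 0.0307 with an estimated correlation). For these 3 lists no gene was lower by DESeq2 or limma-voom either, while 2 glycolysis and hypoxia genes were lower at an unadjusted p under 0.05.

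Inducible effectors and macrophage genes changed in both directions. Mmp14, a membrane-bound matrix protease, rose 4.03-fold, from 16.5 ± 2.67 to 66.6 ± 10.3 CPM, and Saa3, an acute phase protein, rose 7.89-fold to 3.59 ± 0.186 CPM, while the matrix protease Mmp13 was 3.08-fold lower. Of 32 inducible inflammatory enzymes and effectors, 9 were higher and 2 lower (11 and 2 adjusted over the list alone, median 0.27, camera adjusted p = 0.000168, adjusted p = 0.0245 with an estimated correlation). The other lower member, Mmp12, is named after its values were seen. Of 35 macrophage maturation and phagocytosis genes, 16 were higher and 2 lower (16 and 5 adjusted over the list alone, median 0.22, camera adjusted p = 7.99e-05, adjusted p = 0.0733 with an estimated correlation). Marco, a scavenger receptor, was 3.81-fold higher, and Lpl, which splits triglycerides, was 2.79-fold lower, from 1843 ± 60.7 to 661 ± 35.0 CPM. Ctsl, the other lower member, is named after its values were seen. Arg1, which breaks down arginine, rose 3.27-fold. Of 48 interferon-stimulated genes, 11 were higher and 1 lower (19 and 1 adjusted over the list alone, median 0.28, camera adjusted p = 3.17e-07, adjusted p = 0.103 with an estimated correlation), Rtp4 at 2.21-fold and Ifit1 going from 0.174 ± 0.0620 to 0.867 ± 0.197 CPM. The lower member, Stat2, is named after its values were seen. Genes of the NRF2 and haem or iron list, which answer oxidants, were 1 higher and 9 lower of 21 (1 and 12 adjusted over the list alone, median −0.24, camera adjusted p = 2.92e-05, adjusted p = 0.108 with an estimated correlation). Its members Gclm, Me1 and Nqo1 were 1.56-fold, 1.87-fold and 1.73-fold lower, and Trf, the higher member, is named after its values were seen. In the absence of platelet replicate 1, 17 interferon-stimulated genes were higher, and Stat2 was not past the threshold.

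Markers of other blood cells moved with platelet exposure too. Gng11 and Ctla2a, members of the platelet and megakaryocyte list, rose 54.6-fold and 92.3-fold, Gng11 from 1.81 ± 0.229 to 99.5 ± 41.8 CPM. Of 22 tested members, 11 were higher and 1 lower (13 and 1 adjusted over the list alone), with a median of 2.28, or 1.84 with genes absent from untreated cells at their lower bounds (camera adjusted p = 3.04e-18, adjusted p = 0.00354 with an estimated correlation). The lower member was Ppbp, a platelet chemokine that untreated monocytes also held at 242 ± 3.46 CPM, against 174 ± 18.0 CPM with platelets. Of the list, 6 of the 22 markers had at least 1 CPM in untreated cells and 1 is in another list. The erythroid list had 3 of 6 higher, the globin genes Hbb-bs, Hba-a1 and Hba-a2 (4 adjusted over the list alone, camera adjusted p = 0.000148, adjusted p = 0.0245 with an estimated correlation). The basophil and mast cell list had 4 of 8 higher, Mcpt8, Prss34, Gata2 and Hdc (6 higher and 1 lower adjusted over the list alone, median 1.64, camera adjusted p = 0.000168, adjusted p = 0.0245 with an estimated correlation). The dendritic cell list had 3 of 15 higher, Ccr7, Flt3 and Fscn1, each at 0.436 to 2.08 CPM (7 adjusted over the list alone). In platelet replicate 1, Gng11 was at 148 CPM against 77.1 and 73.6 CPM in its replicates and Hba-a1 was at 17.6 CPM against a group mean of 11.6 ± 5.29 CPM. Without that library the same 4 marker lists had 11, 3, 3 and 3 members higher. The mitochondrial ribosomal RNAs mt-Rnr1 and mt-Rnr2 rose 2.76-fold and 2.03-fold and mt-Nd5 was 1.35-fold lower. The list of mitochondrially encoded transcripts as a whole was not past the threshold (2 higher and 1 lower of 10, with mt-Nd5 not past the threshold without platelet replicate 1, adjusted p = 0.685).

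Several fixed lists were not past camera's threshold in this comparison, or were so by few genes. The cytokine and chemokine list had 6 higher and 4 lower of 36 (adjusted p = 0.0804). Ccl5 and Cxcl16 were higher. Il10, an inhibitory cytokine, was 2.77-fold lower and Cxcl3 1.90-fold lower, and Cxcl2 and Ccl9, named after their values were seen, were lower. Tnf, at 26.4 ± 3.29 against 30.9 ± 0.736 CPM, and Cxcl10, at 1.07 ± 0.260 against 0.960 ± 0.263 CPM, were not past the threshold (adjusted p = 0.164 and 0.762). Camera's adjusted p was 0.296 for feedback inhibitors of TLR and NF-kB signalling (2 higher and 2 lower of 26: Socs3 and Il1rn up, Tnip3 and Dusp1 down), 0.994 for pattern recognition receptors (4 higher of 39, Tlr2, Pycard, Clec7a and Nfkb2). It was 0.0578 for alternative activation markers (3 higher of 22: Arg1, Ccl24 and Vegfa). It was 0.309 for classical monocyte markers (3 higher, 2 lower of 21, median −0.01 and mean 0.13), 0.093 for nonclassical markers (3 and 2 of 19), 0.334 for adhesion, migration and chemokine receptors (5 and 4 of 32). It was 0.134 for the TGF-beta response (4 higher of 25: Id2, Bhlhe40, Spsb1 and P2ry12) and 0.994 for immediate early genes (1 lower of 24, Dusp1). The medians of the classical, TGF-beta and immediate early lists change sign with the scaling. The stress response list was past the threshold with 2 of 25 higher, Phgdh and Sdf2l1 (adjusted p = 0.00388, adjusted p = 0.153 with an estimated correlation). The oxidative phosphorylation list was past it at 0.00156 with 0 of 48 genes called by edgeR or limma-voom, 2 by DESeq2 and 2 at an unadjusted p under 0.05. Its adjusted p was 0.611 with an estimated correlation, 0.0616 without untreated replicate 1, and 0.891 with the direction turned without platelet replicate 1. Cytosolic ribosomal proteins had 0 of 57 called by edgeR, DESeq2 or limma-voom, and 0 at an unadjusted p under 0.05 (adjusted p = 0.178). The neutrophil list had Mmp9 higher and Mmp8 lower of 15 (0.134). The B cell list had 0 of 3 called (0.457, 1 at an unadjusted p under 0.05, 0 by DESeq2 and limma-voom), and the stromal and endothelial list had 0 of 7 (0.309, 3 at an unadjusted p under 0.05, 1 by DESeq2, 0 by limma-voom). Of the T and NK cell list only Klrd1 and Ccl5 were tested, and Ccl5 was higher.

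Over all genes, 854 passed edgeR's threshold with platelets against untreated cells, 478 higher and 376 lower, and 229 of them changed at least 2-fold. The count was 439 without untreated replicate 1, 410 without untreated replicate 2, 546 without platelet replicate 2, 415 in a fit of these 6 libraries alone and 1291 by DESeq2. The nonclassical list without platelet replicate 1 had 5 higher and 2 lower, the adhesion list 8 and 3, the neutrophil list 2 and 1, the alternative activation list 3 and 1 and the TGF-beta list 4 and 1. Some lists not past the threshold passed it without 1 library: ribosomal proteins in the higher direction without untreated replicate 3 or platelet replicates 2 or 3 (adjusted p = 0.00897, 0.000678 and 0.002), and in the lower direction without platelet replicate 1 (0.00026, with the median moving from 0.13 to −0.13). The others, each in its direction with all libraries, were alternative activation markers without untreated replicate 2 or platelet replicates 1 or 2 (0.0206, 0.0466 and 0.0436), nonclassical markers and adhesion receptors without platelet replicate 1 (0.00547 and 0.0466), cytokines without platelet replicate 2 (0.0384) and neutrophil markers without untreated replicate 1 (0.0409).

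**Figure D2:**
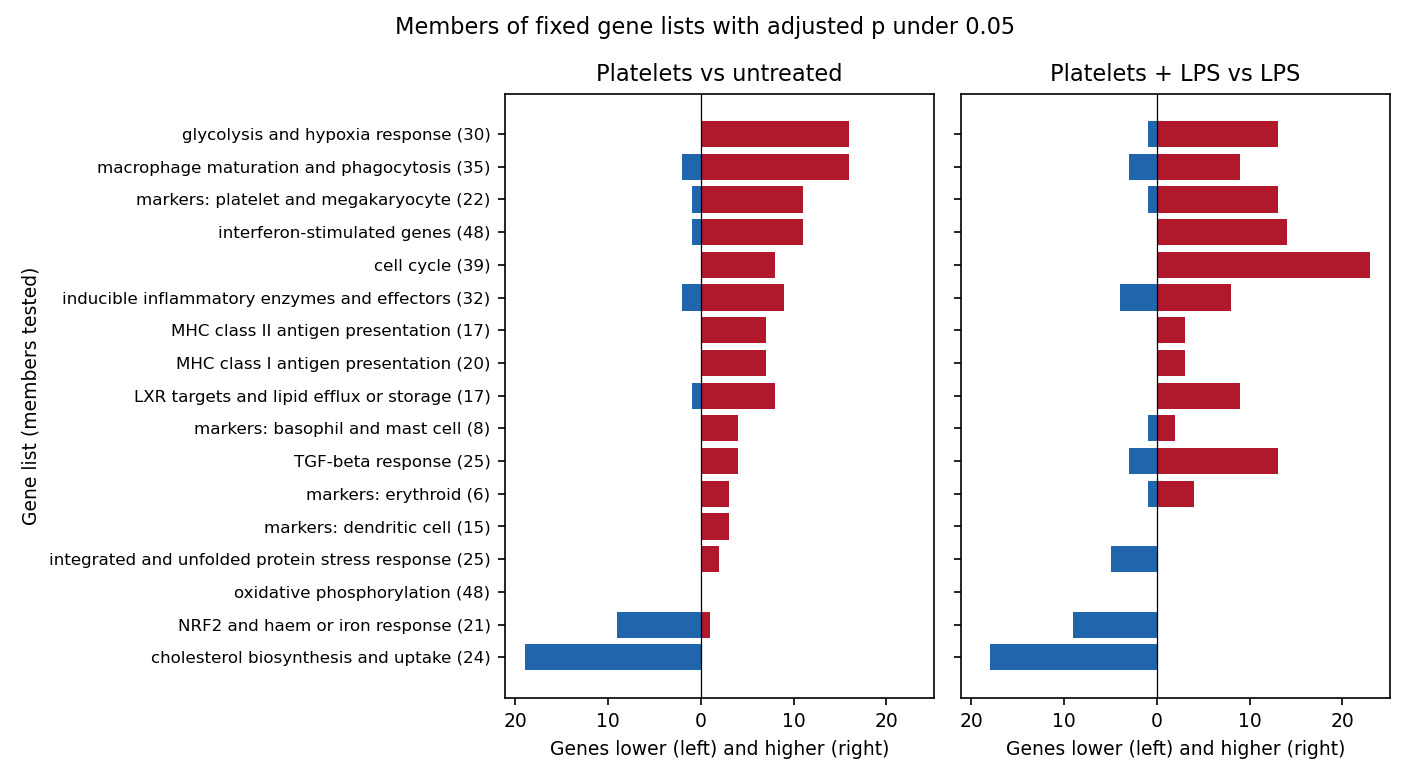
Number of members of each fixed gene list with an edgeR adjusted p under 0.05, higher to the right and lower to the left, for platelet against untreated (left panel) and platelet plus LPS against LPS (right panel). The number of tested members follows each name, and the lists are those past camera's threshold in either comparison. Cholesterol genes were lower in both panels, 19 and 18 of 24, and cell cycle genes higher, 8 and 23 of 39.

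The next comparison asks what LPS changed in monocytes without platelets. Inflammatory and antiviral genes rose. Tnf, an inflammatory cytokine, went from 30.9 ± 0.736 to 1450 ± 79.0 CPM, 46.9-fold (log2 5.55, SE 0.11, adjusted p = 1.57e-15). Il1b and Cxcl10 rose 1053-fold and 4863-fold, Rsad2, an antiviral enzyme, 5025-fold, and Acod1, which makes itaconate, 3245-fold. Of 36 cytokines and chemokines, 32 were higher and 3 lower, with a median of 6.70, or 5.98 with lower bounds (camera adjusted p = 1.76e-16, adjusted p = 0.00822 with an estimated correlation). All 48 interferon-stimulated genes were higher (median 6.18, camera adjusted p = 6.62e-32, adjusted p = 0.00822 with an estimated correlation). Ccl2, which draws monocytes to tissue, was 2.31-fold lower, at 600 ± 54.8 against 1382 ± 108 CPM, and Ccl6 and Ccl7, the other lower chemokines, are named after their values were seen.

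Effector, feedback and MHC class I genes rose with LPS while cell cycle genes fell. Socs3, a brake on cytokine signalling, and Il1rn, the interleukin-1 receptor antagonist, rose 282-fold and 29.4-fold, and 21 of 26 feedback inhibitors were higher and 3 lower (median 2.86, camera adjusted p = 3.31e-10, adjusted p = 0.00941 with an estimated correlation). Of 32 inducible effectors, 30 were higher and 1 lower (median 5.16, camera adjusted p = 5.66e-19, adjusted p = 0.00105 with an estimated correlation), with Ptges, which makes prostaglandin E2, 292-fold higher and Nos2, which makes nitric oxide, at least 1070-fold higher. Tap1, a peptide transporter, rose 16.8-fold, and 17 of 20 MHC class I genes were higher and 0 lower (17 and 1 adjusted over the list alone, by DESeq2 and without platelet replicate 1, median 1.90, camera adjusted p = 1.07e-08, adjusted p = 0.0226 with an estimated correlation). Cdc6 and Ccne2, which act at the start of DNA replication, were 14.3-fold and 6.26-fold lower, and 29 of 39 cell cycle genes were lower and 0 higher (30 and 0 adjusted over the list alone, by DESeq2 and by limma-voom, median −0.61, camera adjusted p = 1.07e-08, adjusted p = 0.0368 with an estimated correlation). The counts of the cytokine, interferon, feedback and effector lists were equal when adjusted over the list alone. Among the largest falls, Angptl4, an inhibitor of lipoprotein lipase, was 60.6-fold lower and Cnr2, a cannabinoid receptor, 55.1-fold lower.

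Receptor and metabolic lists shifted with weaker evidence. Pattern recognition receptors were 29 higher and 4 lower of 39 (30 and 6 adjusted over the list alone, camera adjusted p = 5.22e-08, adjusted p = 0.0582 with an estimated correlation). Tlr2, which senses bacterial lipoproteins, was 16.4-fold higher and Tlr4, the LPS receptor, 3.59-fold lower. The NRF2 and haem or iron list had 16 higher and 2 lower of 21 (0.000327, adjusted p = 0.24 with an estimated correlation), and glycolysis and hypoxia had 19 and 3 of 30 (0.00216, adjusted p = 0.26 with an estimated correlation). Classical monocyte markers had 11 and 2 of 21 (0.0296, adjusted p = 0.297 with an estimated correlation) and dendritic cell markers 9 and 2 of 15 (0.0271, adjusted p = 0.0887 with an estimated correlation). The cholesterol list had 5 higher and 6 lower of 24 (0.394) and the LXR list 5 and 8 of 17 (0.394). Glycolysis and hypoxia without platelet replicate 1 had 19 higher and 5 lower and classical markers 11 and 5. The dendritic call was lost without untreated replicate 3 (adjusted p = 0.0648), platelet replicate 1 (0.0893), LPS replicate 3 (0.112) or platelet plus LPS replicate 2 (0.069). Over all genes 6661 passed the threshold, 3640 higher and 3021 lower, and 3159 changed at least 2-fold. The share that was higher, 54.6%, rests on the scaling. It was 37.9% with upper-quartile factors and 26.3% with library size alone, which moved the median log2 fold change of all genes to −0.19 and −0.37.

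The third comparison asks how monocytes kept with platelets before LPS differed from monocytes given LPS alone. The cholesterol and LXR genes again changed in opposite directions. Cyp51 fell from 98.0 ± 6.34 to 19.9 ± 2.75 CPM, 4.91-fold lower (SE 0.13, adjusted p = 2.21e-08), and Sqle and Msmo1 were 4.53-fold and 4.38-fold lower. Of 24 cholesterol genes, 18 were lower and 0 higher (21 and 0 adjusted over the list alone, median −1.42, camera adjusted p = 8.04e-31, adjusted p = 0.0027 with an estimated correlation). Abca1 rose 8.30-fold to 280 ± 34.3 CPM (SE 0.18, adjusted p = 4.23e-08), Abcg1 25.3-fold, and Nr1h3, which encodes LXR alpha, 2.45-fold. Of 17 genes of the LXR list, 9 were higher and 0 lower (11 and 2 adjusted over the list alone, median 0.76, camera adjusted p = 3.02e-09, adjusted p = 0.0027 with an estimated correlation). No cholesterol gene was higher by DESeq2, limma-voom or at an unadjusted p under 0.05, while 2 of the LXR list were lower by DESeq2 and at an unadjusted p under 0.05, and 10 were higher and 2 lower without platelet replicate 1. Fasn was at log2 −0.60 (adjusted p = 0.0724).

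Cell cycle and TGF-beta response genes were higher with platelets before LPS. Aurka and Plk1, kinases of mitosis, were 1.66-fold and 1.71-fold higher (adjusted p = 0.00011 and 0.000343), and 23 of 39 cell cycle genes were higher and 0 lower (27 and 0 adjusted over the list alone, median 0.45, camera adjusted p = 2.55e-16, adjusted p = 0.00579 with an estimated correlation). DESeq2, limma-voom and an unadjusted p under 0.05 also gave no cell cycle gene lower. Tgfbi, a matrix protein induced by TGF-beta, went from 383 ± 8.37 to 850 ± 16.8 CPM, 2.22-fold higher (SE 0.08, adjusted p = 1.94e-07), and Spsb1 was 3.12-fold higher. Of 25 TGF-beta response genes, 13 were higher and 3 lower (16 and 3 adjusted over the list alone, median 0.52, camera adjusted p = 1.65e-06, adjusted p = 0.00513 with an estimated correlation). The lower members Bambi, Cdkn1a and Cdkn2b are named after their values were seen. The platelet and megakaryocyte markers were 13 higher and 1 lower of 22 (14 and 1 adjusted over the list alone, median 2.32, or 2.14 with lower bounds, camera adjusted p = 8.11e-14, adjusted p = 0.0036 with an estimated correlation), with Gng11 at 64.6 ± 6.74 against 2.01 ± 0.453 CPM and Ppbp the lower member. Erythroid markers were 4 higher (Hbb-bs, Hbb-bt, Hba-a1 and, named after its values were seen, Hba-a2) and 1 lower (Sptb) of 6 (adjusted p = 0.000641, adjusted p = 0.055 with an estimated correlation). Basophil and mast cell markers were 2 higher (Mcpt8 and Prss34) and 1 lower (Ccl3) of 8 (0.0175, adjusted p = 0.138 with an estimated correlation, 0.238 with the stricter filter). They were 3 and 2 without platelet replicate 1, and the platelet markers were 13 and 2.

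Cytokine genes changed in both directions. Ccl2 rose 2.71-fold, from 600 ± 54.8 to 1628 ± 129 CPM (SE 0.10, adjusted p = 2.92e-07), and Ccl7 3.02-fold, while Cxcl5, which attracts neutrophils, was 4.29-fold lower, at 69.0 ± 2.07 against 296 ± 32.2 CPM. In all, 6 of 36 cytokines were higher and 7 lower (7 and 11 adjusted over the list alone, and 7 and 11 without platelet replicate 1, camera adjusted p = 0.847). Tnf was at 1481 ± 71.6 against 1450 ± 79.0 CPM (adjusted p = 0.896), Acod1 at 6705 ± 193 against 6705 ± 390 CPM (1), Il12b at 143 ± 20.2 against 147 ± 9.91 CPM (0.939). Il6 was at 105 ± 14.9 against 136 ± 12.2 CPM (0.0676) and Il1b at 723 ± 60.1 against 1065 ± 31.4 CPM (0.12). Il6 passed the threshold by DESeq2 (0.0369), limma-voom (0.0311) and in the 6 libraries alone (0.0274), and without platelet replicate 1 (0.016) or platelet plus LPS replicate 3 (0.0319). Il1b passed it by limma-voom (0.00368), with no filter (1.32e-05), in the 6 libraries alone (0.00012), and without platelet replicate 1 (0.000669) or 3 (0.0227). Arg1 rose 3.97-fold and Nos2 2.14-fold, and 8 of 32 effectors were higher and 4 lower (adjusted p = 0.765). Ptgs2, which makes prostaglandins, was 2.39-fold lower (adjusted p = 0.00831), but not past the threshold by DESeq2 (0.323) or without platelet plus LPS replicate 2 (0.0628).

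Interferon, antigen presentation, macrophage and metabolic lists passed camera's preset test but not the test with an estimated correlation. Interferon-stimulated genes were 14 higher and 0 lower of 48, among them Rsad2 at 1.46-fold (25 and 0 adjusted over the list alone, camera adjusted p = 1.65e-06, adjusted p = 0.15 with an estimated correlation). MHC class II genes were 3 higher of 17, H2-Aa, H2-Ab1 and Ctss (6 adjusted over the list alone, 0.0094, adjusted p = 0.325 with an estimated correlation, 0.0511 with the stricter filter), beside dendritic cell markers with a median of 0.31 (adjusted p = 0.264). MHC class I genes were 3 higher of 20, B2m, Tap1 and H2-T22 (6 adjusted over the list alone, 0.000197, adjusted p = 0.101 with an estimated correlation). H2-Ab1 itself had an adjusted p of 0.039, and of 0.0507 to 0.149 without untreated replicates 2 or 3 or any LPS or platelet plus LPS library. Macrophage genes were 9 higher and 3 lower of 35 (14 and 6 adjusted over the list alone, 0.00679, adjusted p = 0.211 with an estimated correlation). Lpl was 2.73-fold lower. Glycolysis and hypoxia genes were 13 higher and 1 lower of 30, with Hk2 and Vegfa at 1.80-fold and 2.74-fold (19 and 1 adjusted over the list alone, 8.63e-08, adjusted p = 0.0777 with an estimated correlation). NRF2 and haem or iron genes were 9 lower and 0 higher of 21, with Slc40a1, the iron exporter, 2.21-fold lower (10 and 0 adjusted over the list alone, 6.07e-06, adjusted p = 0.133 with an estimated correlation). Without platelet replicate 1 the genes higher were 25 interferon-stimulated, 5 MHC class II, 6 MHC class I and 15 macrophage genes, with 6 macrophage genes lower. No interferon-stimulated gene was lower, and no NRF2 gene higher, by DESeq2, limma-voom or at an unadjusted p under 0.05.

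Among the lists not past the threshold were feedback inhibitors (5 higher and 0 lower of 26, with 1 lower by DESeq2 and limma-voom, adjusted p = 0.641), pattern recognition receptors (2 and 2 of 39, 0.0535), the stress response (0 and 5 of 25, with Trib3 3.73-fold lower and 2 higher by DESeq2, 0.294) and immediate early genes (3 and 1 of 24, 0.436). Among the genes of these lists Dusp4, a phosphatase of MAP kinases, rose 2.56-fold and Il1rn 1.73-fold. The receptors called without platelet replicate 1 were 3 higher and 6 lower, the immediate early genes 5 and 1, the feedback inhibitors 5 and 3, and the stress response genes 3 and 6. The receptor list passed the threshold without platelet replicate 1 (0.0458), platelet replicate 2 (0.0446) or LPS replicate 2 (0.0294). Over all genes 957 passed the threshold, 580 higher and 377 lower, 213 of them at least 2-fold. Without platelet replicate 1, which lies outside this pair of groups, the count was 1640. It was 628 without LPS replicate 3, and 597 and 557 without platelet plus LPS replicates 1 and 2.

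**Figure D3:**
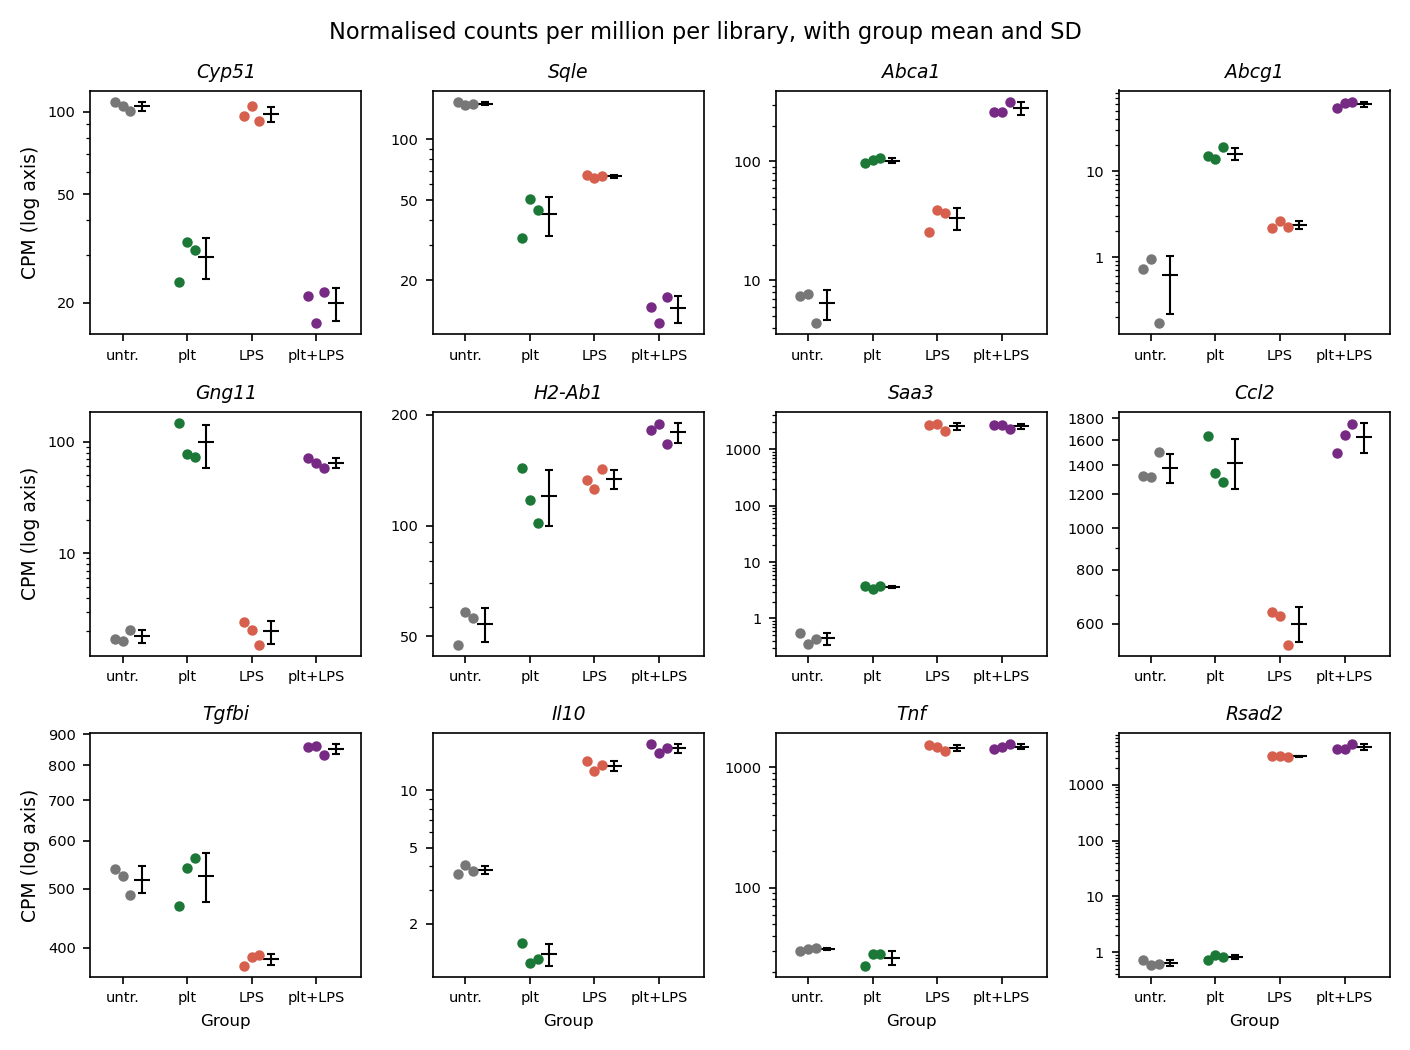
CPM on a log axis for 12 of the named genes in untreated (untr.), platelet (plt), LPS and platelet plus LPS (plt+LPS) monocytes. Points are libraries, and the bar beside them is the group mean ± SD (n = 3). Cyp51 and Sqle were lower and Abca1, Abcg1 and Gng11 higher in both platelet-exposed groups, while Ccl2 stood at 600 CPM with LPS alone and 1382 to 1628 CPM in the other 3 groups.

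The fourth comparison gives the LPS response of monocytes kept with platelets. Tnf rose 56.1-fold, from 26.4 ± 3.29 to 1481 ± 71.6 CPM (SE 0.11, adjusted p = 1.05e-15), and Rsad2 5745-fold. Il10 rose by 3.58 on the log2 scale. Of 36 cytokines, 33 were higher and 1 lower (median 6.63, or 6.27 with lower bounds, camera adjusted p = 7.87e-19, adjusted p = 0.00588 with an estimated correlation). The lower member, Ccl6, is named after its values were seen. Higher as well were all 48 interferon-stimulated genes (2.18e-32), 23 of 26 feedback inhibitors (2 lower, 1.11e-12) and 30 of 32 effectors (0 lower by edgeR, DESeq2, limma-voom and at an unadjusted p under 0.05, 6.95e-19). For these 3 lists, in that order, adjusted p = 0.00588, 0.00588 and 0.00106 with an estimated correlation. MHC class I genes were 16 higher of 20 (1.11e-08, adjusted p = 0.0221 with an estimated correlation). Ccl2 was at 1628 ± 129 against 1420 ± 190 CPM (adjusted p = 0.125, 0.0151 without platelet replicate 1). Among the largest falls, Sox4, a transcription factor, was 32.2-fold lower and Plau, the urokinase protease, 28.9-fold lower.

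Other lists passed only the preset test in this comparison. Cell cycle genes were 19 lower and 0 higher of 39 (0 higher by DESeq2 and limma-voom, 1 at an unadjusted p under 0.05), with a median of −0.32 (camera adjusted p = 5.63e-06, adjusted p = 0.0881 with an estimated correlation). Pattern recognition receptors were 29 higher and 5 lower of 39 (1.18e-07, adjusted p = 0.0747 with an estimated correlation) and NRF2 and haem or iron genes 16 and 3 of 21 (0.000688, adjusted p = 0.245 with an estimated correlation). Glycolysis and hypoxia genes were 17 higher and 4 lower of 30 (0.0159, adjusted p = 0.335 with an estimated correlation, 0.0559 and 0.0991 with upper-quartile factors and library size alone, and a median of −0.02 under the latter). Immediate early genes were 14 and 6 of 24 (0.0175, adjusted p = 0.216 with an estimated correlation) and classical markers 12 and 2 of 21 (0.0308, adjusted p = 0.301 with an estimated correlation). Platelet markers were 1 higher and 8 lower of 22 (median −0.55, 0.0342, adjusted p = 0.245 with an estimated correlation, 0.118 and 0.167 with upper-quartile factors and library size alone, 0.0526 without platelet replicate 2). Cholesterol genes were 3 higher and 10 lower of 24 (0.0451, adjusted p = 0.404 with an estimated correlation), with 0.0504 to 0.106 without any LPS library, platelet replicates 2 or 3, or platelet plus LPS replicates 1 or 2. Without platelet replicate 1 platelet markers were 1 higher and 5 lower and classical markers 12 and 4. In all 6498 genes passed, 3627 higher and 2871 lower, and 2984 changed at least 2-fold. The higher share of 55.8% became 35.4% with upper-quartile factors and 27.6% with library size alone.

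The interaction asks for which genes the platelet effect differed with and without LPS. Il10 was 2.77-fold lower with platelets alone, and at 16.5 ± 0.910 CPM with both against 13.4 ± 0.835 CPM with LPS (adjusted p = 0.213), so that the effects differed by 3.40-fold (log2 1.77, SE 0.20, adjusted p = 0.000229). Ccl2 and Ccl7, chemokines for monocytes, differed by 2.64-fold and 2.46-fold, and Cx3cr1, a gene of nonclassical monocytes, by 2.71-fold. Saa3, Mmp14 and Marco went the other way, with log2 interactions of −2.96, −1.79 and −1.86. Each rose with platelets alone, but from levels far below those under LPS. In all 208 genes passed the threshold, 113 with a positive and 95 with a negative interaction. The count was 361 without platelet replicate 1 and 87 to 135 without any other single library except platelet replicate 3 and LPS replicate 3.

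Gene sets defined by LPS in these same libraries were tested with platelets under LPS, and not all of them moved in a single direction. Of 3752 genes that fell with LPS on average, 287 were higher and 72 lower with platelets plus LPS than with LPS alone (median 0.08, camera p = 0.000417, p = 0.00589 with an estimated correlation). Of the 436 that fell at least 4-fold, 54 were higher and 8 lower (median 0.35, p = 5.18e-05, p = 0.0121 with an estimated correlation). Of 4288 genes that rose with LPS, 179 were higher and 245 lower (median −0.05, p = 0.000679, p = 0.031 with an estimated correlation, 0.0653 by fry), and of the 1088 that rose at least 4-fold, 79 were higher and 92 lower (median 0.00, p = 0.388). The sets were chosen on the libraries in which they were tested, so these counts are not independent evidence.

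Averaged over both LPS levels, cholesterol genes were lower and genes of the LXR list higher with platelets, and the platelet effects of single genes were correlated between LPS levels. Of 24 cholesterol genes, 21 were lower and 0 higher (median −1.47, camera adjusted p = 3.1e-30, adjusted p = 0.00255 with an estimated correlation), and of 17 genes of the LXR list 9 were higher and 1 lower (median 0.71, 4.01e-08, adjusted p = 0.00255 with an estimated correlation). Cell cycle genes were 24 higher of 39 (2.22e-14, adjusted p = 0.0112 with an estimated correlation) and interferon-stimulated genes 22 of 48 (5.47e-09, adjusted p = 0.0677 with an estimated correlation). Across the 13151 genes, the platelet effect with LPS and that without had r = 0.49 (Spearman's rho 0.36), and the LPS effect with platelets and that without r = 0.93 (rho 0.86). Genes are not independent replicates, but the paired contrasts share no library. Of genes called in both platelet comparisons, 216 were higher in both, where 21.1 would be if the calls were independent, and 120 were lower in both (10.8). Of these genes 15 of 351 had opposite signs. On average over both LPS levels 1660 genes passed the threshold for platelets, 935 higher and 725 lower, and 8040 for LPS, 4288 higher and 3752 lower.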

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

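The tests of the interaction were planned, while the tests of explanations and the counts over other splits of the libraries were chosen only after the results were seen. The results below had a platelet effect that differed between monocytes with and without LPS by a test of the difference itself. In all 208 genes did so. Among the largest positive log2 interactions were Usp2 at 1.87, Il10 at 1.77, Dusp4 at 1.66, Arl4c at 1.51, Pdgfa at 1.47 and Cd72 at 1.46, and the chemokine gene Ccl2 was at 1.40. Arl4c had an adjusted p of 0.0199, which was 0.0521 to 0.061 without LPS replicates 1, 2 or 3 or platelet plus LPS replicates 2 or 3, and 0.133 by limma-voom. The negative ones were Ccl5 at −4.66, Clec1b at −4.44, Saa3 at −2.96, Ccr7 at −2.89, Bcl2a1a at −2.31, the antiviral gene Ifit1 at −2.06 and the MHC class II gene H2-Ab1 at −0.74. Clec1b had 4 counts over the 3 untreated libraries and 51 over the 3 LPS libraries, so its value rests on a low baseline. Platelets added 18.6 CPM of Clec1b without LPS and 11.6 CPM with LPS. Ifit1 was also low in untreated cells. Il1a, with 1 count over the 3 untreated libraries, had an adjusted p of 0.007855. H2-Ab1 had an adjusted p of 0.0373, which was 0.0628 to 0.118 without any single library other than platelet replicates 1 or 3, and Bcl2a1a one of 0.0487, which was 0.0653 to 0.209 without any other than untreated replicate 3, platelet replicate 1 or LPS replicate 3. By limma-voom the adjusted p was 0.0538 for Il1a, 0.0554 for Ifit1 and 0.346 for Bcl2a1a.

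Among the gene lists, the interaction had a camera adjusted p of 6.65e-05 for MHC class II (0 higher, 2 lower of 17: H2-Aa and H2-Ab1), 0.000891 for inducible effectors (1 and 8 of 32) and 0.00158 for the TGF-beta response (4 and 0 of 25: Smad6, Tgfbi, Olfml3 and Tgfb1). It was 0.000163 for the cell cycle list, with 0 of 39 genes called by edgeR, DESeq2 or limma-voom and 12 at an unadjusted p under 0.05, and 0.000447 for the stress response (0 and 3 of 25: Trib3, Phgdh and Herpud1). It was 0.0101 for glycolysis and hypoxia (0 and 2 of 30: Bnip3 and Egln3), with 0.0794 and 0.0529 without platelet replicates 2 and 3. It was 0.0399 for cholesterol genes (0 and 2 of 24: Msmo1 and Sc5d), with 0.0503 to 0.239 without any single library other than platelet replicate 1, LPS replicate 1 or platelet plus LPS replicate 3. For oxidative phosphorylation it was 0.0402, with 0 of 48 called by edgeR, DESeq2 or limma-voom or at an unadjusted p under 0.05, 0.0757 to 0.346 without untreated replicates 1 or 2, LPS replicates 1 or 2 or platelet plus LPS replicates 1 or 3, and 0.525 with the direction turned without platelet replicate 1. It was 0.000163 for platelet markers (0 and 2 of 22: Clec1b and Alox12, each with 4 counts over the untreated libraries) and 0.00431 for dendritic cell markers (0 and 1 of 15: Ccr7), the latter 0.0928 and 0.13 without platelet replicate 1 and LPS replicate 3. Without platelet replicate 1 the genes called were 0 and 4 for MHC class II, 2 and 9 for effectors, 0 and 5 for cholesterol genes, 6 and 1 for the TGF-beta response, 1 and 6 for glycolysis and hypoxia, 0 and 5 for the stress response and 0 and 2 for dendritic cell markers. With an estimated correlation none of these 10 lists passed the threshold (adjusted p = 0.0811 to 0.781). Genes that rose with LPS had a camera interaction p of 0.028 (31 called higher, 87 lower of 4288), those that fell 0.0125 (70 and 7 of 3752), those that rose at least 4-fold 0.000432 (5 and 59 of 1088) and those that fell at least 4-fold 0.000698 (16 and 1 of 436). The first p was 0.0884, 0.122, 0.18, 0.077 and 0.103 without untreated replicate 3, platelet replicates 2 and 3, LPS replicate 3 and platelet plus LPS replicate 2.

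For each comparison of 2 groups, 1 of the 10 splits of the 6 libraries, the real one, gave as many genes: 854, 6661, 957 and 6498 genes, in the order platelet against untreated, LPS against untreated, and platelet plus LPS against LPS and against platelet, where the highest other splits gave 0, 0, 1 and 0. With 10 splits a share under 0.05 cannot be reached. For the average platelet effect 1 of 100 splits, the real one, gave as many as 1660 genes (highest other 223). For the average LPS effect the real split alone gave as many as 8040 (highest other 1833). A random division of these libraries is argued against for both. The splits cannot speak to chance between mice or cultures, since the labels do not say what the libraries of a group are. For the interaction 2 of 100 splits gave as many as 208 genes, but exchanging platelet labels does not keep the platelet effect itself in place, so this count says nothing about chance. The other of the 2, with 1660 genes, keeps the true groups and exchanges the platelet labels at a single LPS level, which turns the average platelet effect into an interaction.

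Platelet marker transcripts were higher in exposed libraries, and RNA carried in by platelets that stayed on or in the washed monocytes is a candidate source. Platelet replicate 1 alone is argued against, since 11 markers were higher without it, as with it. The CPM that exposure added with LPS, divided by that added without, was 0.404 to 0.693 for the 11 markers that rose without LPS. The SD of its log2, 0.273, lay below its median standard error of 0.356. This cannot decide the source, since a common response of the cells could give a single ratio too. The standard errors also hold spread between libraries that the markers share, such as the high marker levels of platelet replicate 1. The SD over markers does not hold that spread. Ppbp went the other way, at 174 CPM with platelets against 242 CPM, and at 140 against 253 CPM with LPS. Markers too low to be tested mostly had more counts in the platelet than the untreated libraries. Tubb1 had 14 against 2, Tmem40 44 against 4, Cavin2 32 against 0 and Gata1 19 against 1. Selp had 5 against 0, Gp1bb 1 against 0, and Gp5 0 in both. With LPS, Selp was lower with platelets, at 5 against 14, Gp1bb had 0 in both, and the others were higher. All lay far below the 15233 counts of Ctla2a in the platelet libraries. Pf4, at 4124 ± 1401 against 3843 ± 365 CPM without LPS, varied too much to argue either way. With LPS, Pf4 had 267827 unscaled counts over the exposed libraries against 298084 over the others, and was not past the threshold. The fall of Ppbp does not decide the source, since a fall within the monocytes could hide added RNA. Carried-in RNA and a change within the monocytes or other cells cannot be told apart, because untreated monocytes already hold Ppbp and Pf4 and no library of platelets alone was sequenced.

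Cholesterol genes were lower and genes of the list of LXR targets and lipid efflux or storage higher with platelets. RNA carried in by platelets is argued against for the cholesterol genes, since it would dilute all genes alike while their median was −1.28. For the LXR targets Abca1, Abcg1, Mylip and Nr1h3 it is argued against as the only source of the CPM added with LPS. Their ratios of added CPM (2.59, 3.74, 2.59 and 3.85) lay above the highest marker by over 2 standard errors. They raised the mean log2 CPM added to the 8 list members that rose, over that added to the markers, from 2.80 (SD 0.216) without LPS to 4.21 (SD 0.158) with LPS. The difference was 1.41, where a single source would give none. These ratios do not test whether the CPM of these 4 genes added without LPS was carried in. For the other 4 members, whose ratios were not above the highest marker by 2 standard errors (Apoe, Scd2, Hilpda and Pltp, at 0.539, 0.568, 0.625 and 0.815), carried-in RNA cannot be told apart from a change in the monocytes, because the marker ratio alone does not show the source. Scaling between libraries is argued against, as a scaling factor would move all genes alike, while the median of the cholesterol list minus that of all genes was −1.28. A response of the monocytes to platelets, the biological explanation the design names, and other material in the platelet preparation such as plasma lipoproteins stay open as untested, and this may be settled only with a control for that material.

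Of the 1088 genes that rose at least 4-fold with LPS, 59 passed the threshold with a negative interaction. Reads from LPS libraries appearing in the platelet libraries are argued against: the 30 most abundant LPS-induced genes with under 2 CPM in untreated cells gained 0.0487% of their LPS level (SD 0.00443, n = 3), while the 58 of the 59 genes with a higher mean with platelets alone than in untreated cells, which the selection favours, needed a median of 3.49% and a lower quartile of 1.36%. Endotoxin in the platelet preparation cannot be told apart from an effect of platelets: with platelets alone 108 of the 1088 genes were higher and 40 lower, with a median of 0.06 against 0.00 for other genes, and Tnf and Cxcl10 were not past the threshold. It stays open because a low dose need not raise every LPS-induced gene, and no library tests the platelet preparation without platelets. A priming effect of platelets is a hypothesis that these data do not test apart from it.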

How the results depend on the processing

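The scaling and filter alternatives for the lists and sets, and the list counts without platelet replicate 1, were chosen only after the data were seen, while the other alternatives were planned. A tally over the alternatives other than a minimum log2 fold change took the largest rises and falls and the genes fixed in advance. The other genes named, such as members of a list, were not in it. Of the 4523 values tallied, 4370 kept their side of the threshold. Of the rest, 80 were no longer past it and 73 became so, and 0 reversed. Reversal was checked only for genes past the threshold in the main analysis. For the lists the counts, in that order, were 3958 of 4193, 114, 114 and 2, and 5 others became past the threshold in the opposite direction. The 2 that reversed are oxidative phosphorylation without platelet replicate 1, at 0.891 for platelet against untreated (0.00156 in full, range without 1 library 1.07e-05 to 0.891) and 0.525 for the interaction (0.0402 in full, 0.000516 to 0.525). That library had 0.886% mitochondrial counts, and the cause was not tested.

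With an absolute log2 fold change of at least 1, which removes smaller changes by construction, the counts of genes were 229 for platelet against untreated, 3159 for LPS against untreated, 213 and 2984 for platelet plus LPS against LPS and against platelet, 75 for the interaction, and 236 and 3234 for the average platelet and LPS effects. DESeq2 gave 1291 genes for platelet against untreated and 403 for the interaction, no filter 371 for the interaction over 26048 genes, and a fit of the 6 libraries alone, with fewer samples, 415 for platelet against untreated. The cause was not tested for DESeq2 and the filter. Without 1 library in turn the counts ran from 410 to 1027, 5906 to 7426, 557 to 1640, 5835 to 6754, 87 to 361, 1163 to 1993 and 7731 to 8461, in the order platelet against untreated, LPS against untreated, platelet plus LPS against LPS and against platelet, interaction, and average platelet and LPS effects. The count for platelet against untreated was 439, 410 and 546 without untreated replicates 1 and 2 and platelet replicate 2. That for platelet plus LPS against LPS was 1640 without platelet replicate 1, 628 without LPS replicate 3, and 597 and 557 without platelet plus LPS replicates 1 and 2. The interaction count was 361 without platelet replicate 1, 116, 87 and 135 without untreated replicates 1, 2 and 3, 122 without platelet replicate 2, 98 and 121 without LPS replicates 1 and 2, and 114, 113 and 115 without platelet plus LPS replicates 1, 2 and 3; the cause was not tested.

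With a replicate block the counts were 621, 6359, 726, 6210, 118, 1383 and 7829 in that order. The labels do not say that equal numbers pair the libraries. Of 18 correlations between same-numbered libraries of different groups, after group means were removed, 1 exceeded 0.1 (range −0.228 to 0.14). The values thus give no sign of pairing, but with so few libraries per group they cannot exclude it. A block costs degrees of freedom, and whether that lowered the counts was not tested.

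Camera with an estimated correlation left 6 lists past the threshold of 11 for LPS against untreated, 5 of 13 for platelet plus LPS against LPS, 5 of 13 against platelet, 0 of 10 for the interaction (10 with the preset correlation), 10 of 17 for the average platelet effect and 5 of 11 for the average LPS effect, since lists whose genes vary together lose evidence. For platelet against untreated it left 11 of 16. Fry, which does not compare a list with other genes, gave 24, 27 and 25 lists for LPS against untreated, platelet plus LPS against platelet and the average LPS effect. The set of genes that rose with LPS had an interaction p of 0.236 with no filter, 0.13 with an estimated correlation, 0.407 by fry, and 0.000239 to 0.18 without 1 library, lost without untreated replicate 3 (0.0884), platelet replicates 2 (0.122) and 3 (0.18), LPS replicate 3 (0.077) and platelet plus LPS replicate 2 (0.103). In platelet plus LPS against LPS it had 0.0653 by fry. The correlation of platelet effects, 0.49 in full, was 0.576 with the stricter filter and 0.403 to 0.454 without 1 library, and that of LPS effects, 0.93, was 0.96 and 0.900 to 0.913. The genes tested numbered 13475 to 13618 without 1 library and 11483 with the stricter filter, against 13151, and the cause was not tested. Under library size alone the median log2 fold change of all genes moved to −0.37, −0.34 and −0.36 for LPS against untreated, platelet plus LPS against platelet and the average LPS effect, so the number higher against lower with LPS rests on the scaling. Depth limits genes near 3 counts per library, 0.0854 to 0.1635 CPM.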

Other observations

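The genes in this part were chosen only after the values were seen. The 5 genes that follow, which are outside the fixed lists, were higher with platelets at both LPS levels. Ctsk, a collagen-degrading protease, rose 3.62-fold without LPS (8.72 ± 0.657 to 31.6 ± 0.630 CPM, edgeR adjusted p = 2.51e-07) and 3.30-fold with LPS (adjusted p = 8.6e-07). Timp2, an inhibitor of matrix proteases, rose 3.15-fold and 2.60-fold (adjusted p = 7.8e-08 and 5.02e-07). Olr1, a receptor for oxidised low-density lipoprotein, rose 2.16-fold (adjusted p = 0.00315) and 3.52-fold (adjusted p = 1.12e-06), from 19.7 ± 1.98 to 69.4 ± 5.61 CPM with LPS. Plpp3, a lipid phosphatase, rose 2.35-fold and 2.96-fold (adjusted p = 7.28e-06 and 2.53e-07). Gatm, the first enzyme of creatine synthesis, rose 2.11-fold and 4.12-fold (adjusted p = 8.27e-06 and 1.57e-08).

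Cd226, an adhesion receptor that platelets also carry, was at 8.53 ± 1.47 CPM with platelets against 0.0351 CPM without (n = 3 each), and at 6.20 ± 0.428 against 0.0362 CPM with LPS. Clu, an extracellular chaperone, was at 8.78 ± 0.775 against 0.0113 CPM, and at 4.86 ± 0.291 against 0.0727 CPM with LPS. The unexposed levels of both genes lie below 3 counts per library. Whether their RNA came from platelets or monocytes was not tested.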
